A study of Mus musculus with 2 samples.

How the data were processed

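Gene expression was measured by Affymetrix array in CD8 single-positive thymocytes of mice aged 8 weeks. Per the labels' protocols, thymocytes were isolated by magnetic sorting, RNA of 2 to 4 thymuses of the same genotype was pooled, ribosomal RNA was depleted, and the RNA was amplified, fragmented and labelled with biotin by Affymetrix whole-transcript kits. There is 1 array of CIITAtgpIV-/- thymocytes and 1 array of B6 wild-type thymocytes. Each group therefore has 1 sample, no difference between the groups has a replicate check, and no p-value is given.

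The authors' deposited value table holds a log2 signal for each of 35556 probe sets in each array. The submitters' processing notes name GCOS and RMA (robust multi-array average, which corrects background, equalises probe distributions between arrays and summarises probes to a log2 value). The series' design text names Expression Console 1.1 and the R package affy 2.9.2, with selection at a fold change of 2 and a false discovery rate of 10%. The array type, annotation release and genome build are not given in the sources used here. RMA compresses differences at low signal, so a fold against a dim value tends to be understated.

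The authors' deposited table lists 1003 probe sets with their log2 ratio and annotation, and holds no false discovery rate. Every one of its 1003 ratios equals the CIITAtgpIV-/- minus B6 wild-type difference of the value table within 0.1, which fixes the direction of the ratio. All 1003 are of the category main and differ by at least 2-fold. The identifiers run from 10345436 to 10607475, and the value table has no other probe set past 2-fold within that range, which holds 28560 probe sets. The 6996 probe sets outside that range are not annotated in the files used here. The 2 signal columns of the authors' deposited table were not used, since the value table gives the levels.

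Gene names come only from the authors' deposited table. Of its 1003 probe sets, 932 carry 1 gene symbol, 0 carry several and 71 carry none. Symbols were updated through a RefSeq gene table of the mouse assembly GRCm38.p6 for 876 probe sets, which changed 160 symbols, and the rest kept the file's symbol. Of the 752 genes on the same chromosome in both sources, 93 overlapped in position, so the file's coordinates are not those of GRCm38. They are given below as the file states them, with the build unknown. Probe sets that differ by less than 2-fold, the 71 listed ones without a symbol and all those outside the listed range have no gene name in the files used here. For a member of a gene list that is not listed, the size of the difference is therefore unknown. It was under 2-fold if the gene's probe sets lie inside the listed range and are not among those 71.

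A gene was represented by its listed probe set with the highest mean signal. Genes counted as past the expression floor had a higher value of at least 5.42 on the log2 scale, the median over all probe sets of the higher of both values. The threshold was 2-fold. As the only available yardsticks of error, the robust standard deviation (SD, the median absolute deviation scaled to match the SD of a normal distribution) of the difference over the 28560 probe sets was 0.25 on the log2 scale, and each named gene's difference was set against those of the 500 probe sets nearest to it in mean signal. Both mix measurement error, differences between the pooled mice and differences between the genotypes, which 1 array per group cannot separate. Neither gives the variation of a single gene between mice. The share among the 500 nearest is a rank by size, since these probe sets include changed ones.

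A set of 26 gene lists was fixed before the data were examined. They covered MHC class II, MHC class I presentation, memory-like CD8 cells, cytotoxic effectors, NK receptors, the response to IL-4 and STAT6, PLZF-expressing innate T cells, immature double-positive thymocytes, late thymic maturation, T cell receptor signalling, the CD8 and CD4 lineages, core T cell genes, the interferon response, the cell cycle, early stress, chemokine receptors, regulatory T cells, gamma delta T cells, B cells, myeloid and dendritic cells, granulocytes, thymic epithelium, red cell precursors, mitochondrial transcripts and ribosomal proteins. For each list the median difference of its listed members past the floor was ranked among 10000 random lists of the same size, drawn from the listed genes past the floor and matched on mean signal in 20 bins. The design had foreseen all genes of the array as the background, which the missing names prevented. The percentile therefore describes direction and size within the authors' selection of changed genes, in these 2 libraries.

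Named genes followed a rule fixed before the data were examined: the 12 with the largest increase and the 12 with the largest decrease past the floor (leaving out unnamed gene models and receptor segments), up to 4 members of each list with the largest difference past the floor, and Ciita, Cd8a, Cd4, Eomes, Zbtb16, Il4, Cd74 and H2-Ab1 in any case. Not every gene that the rule selects is reported here by name. Other members of a list are named where the list is described, and these were chosen after their values were seen. Alternatives were no floor, a floor at the 75th percentile, thresholds of 1.5-fold and 3-fold, median centring, quantile normalization, loess with a span of 0.3, the mean over the probe sets of a gene, and a window of 20 Mb in place of 5 Mb around Ciita. Counting probe sets with identical values once was added after seeing the data. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. Tested on simulated data for 28560 probe sets with noise of the observed robust SD, the 2-fold threshold was passed by 98% of probe sets raised 3-fold, by 4.0% of those raised 1.5-fold and by 0.0071% of unchanged ones. The simulated noise was the same at every signal. The observed robust SD was 0.30 from the floor to the 75th percentile of signal and 0.36 above it. The share of unchanged probe sets passing is therefore understated above the floor.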

Results

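Messenger RNA levels were compared between CD8 single-positive thymocytes of CIITAtgpIV-/- mice and of B6 wild-type mice, with 1 array of pooled thymuses for each. CIITA is the transactivator that switches on MHC class II genes, and the genotype name denotes a CIITA transgene together with loss of promoter IV of Ciita. The comparison asks how the CD8 single-positive population of these mice differs from that of wild-type mice. Log2 signals had a median of 5.20 in the wild-type array, with quartiles at 3.88 and 7.33, and a median of 5.30 in the CIITAtgpIV-/- array, with quartiles at 3.97 and 7.32. The arrays correlated at r = 0.976 across the 35556 probe sets, which are not independent replicates. With 1 array per group there was no replicate check on any difference below, and the number of arrays limits the precision.

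The CIITAtgpIV-/- library carried more RNA for MHC class II, for genes of memory-like CD8 cells and for Klra (Ly49) receptors, and less RNA for genes of immature thymocytes and of the cell cycle. It also carried less haemoglobin and myeloid RNA, which CD8 cells do not make, with Hbb-b1 differing by -3.81 and Lyz2 by -2.94 on the log2 scale. Among genes past the expression floor, 199 were at least 2-fold higher in CIITAtgpIV-/- and 541 were at least 2-fold lower. At 8-fold or more, 18 genes were higher and 74 were lower. Counted as probe sets, with those that carry no gene symbol included, 254 were higher and 683 lower past the floor. Of the 28560 probe sets in the range that the authors listed from, 3.51% passed 2-fold, and the median difference over the range was 0.03 on the log2 scale with a robust SD of 0.25. The spread grew with signal, from a robust SD of 0.20 below the floor to 0.36 above the 75th percentile of signal.

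**Figure D1:**
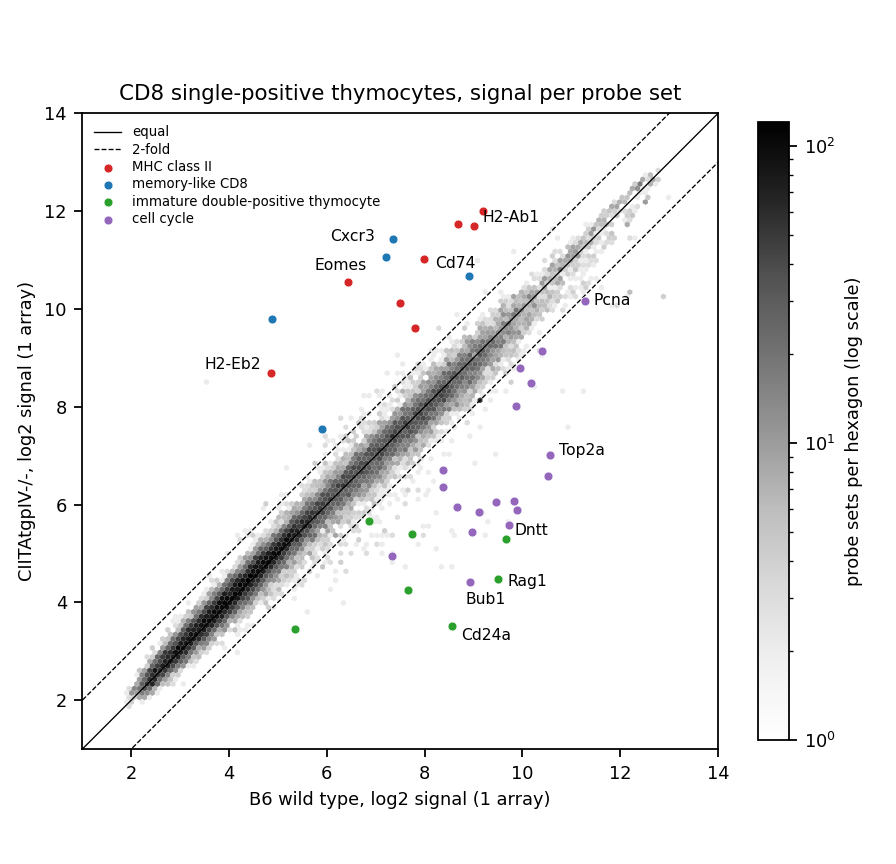
Log2 signal of each probe set in the listed identifier range in B6 wild type (x axis) against CIITAtgpIV-/- (y axis), 1 array each, with grey hexagons shaded by the number of probe sets on a log scale, a solid line at equality and dashed lines at 2-fold. Coloured points are the listed members of 4 gene lists, with the MHC class II and memory-like CD8 genes above the upper dashed line and the immature thymocyte and cell cycle genes below the lower one.

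MHC class II genes, which the CIITA protein controls, were higher in CIITAtgpIV-/- in all 8 listed members of the 12 on the list. Cd74, the invariant chain that escorts class II molecules, had a log2 signal of 8.00 in wild type and 11.0 in CIITAtgpIV-/-, an 8.10-fold difference. H2-Ab1, a class II beta chain, was 6.47-fold higher, reaching 11.7, and H2-Eb1 was 8.37-fold higher. The differences of H2-DMb2, a chain of the peptide exchange factor, and H2-Eb2 were 4.13 and 3.84 on the log2 scale. The list's median difference was 2.92, above all 10000 matched random lists of listed genes, whose median was -1.16. The wild-type signal of H2-Aa, at 9.19, was already above 7.50, the 75th percentile over all probe sets of the higher of both values, and so was that of H2-Ab1. Ciita itself was not among the listed genes, so its level is not reported here. The file places Cd74 on chromosome 18 (60963502 to 60983106) and H2-Ab1 on chromosome 17 (34400185 to 34406355). None of the 14 genes for class I presentation was listed. The class Ib genes H2-Q6, H2-Q8 and H2-Q10, which are not on that list, were higher by 1.76, 1.37 and 1.15, as described further below.

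Genes of memory-like CD8 cells were higher in CIITAtgpIV-/- in all 5 listed members of the 14 on the list. Eomes, a transcription factor of memory CD8 cells, was 14.5-fold higher, from 7.20 to 11.1. Cxcr3, a chemokine receptor of effector and memory T cells, was 16.9-fold higher. Il2rb, the beta chain of the receptors for IL-2 and IL-15, was 3.41-fold higher, and Cd44, an adhesion receptor of antigen-experienced T cells, was 3.12-fold higher. NK cells also carry several transcripts of this list and of the cytotoxic list below, and all 6 listed probe sets of the Klra receptors, which NK cells carry too, were higher in the same library. None of the 12 genes on the NK receptor list was listed, and whether NK cells contributed was not tested. The median of the memory-like list, 3.86, lay at percentile 99.995 of the random lists. Among the 500 probe sets nearest to each in mean signal, none differed by as much as Eomes or Cxcr3, while 1.2% differed by as much as Il2rb. Eomes lies on chromosome 9 (118387330 to 118395250) and Cxcr3 on chromosome X (98926874 to 98929486) in the file's coordinates. Tbx21 and Il7r were among the 9 members that were not listed.

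Of the 15 cytotoxic effector genes, 5 were listed as higher and 1 as lower. Prf1, the pore-forming protein perforin, was 3.70-fold higher, and Fasl, the death ligand of T cells, was 3.89-fold higher. The chemokine genes of the list moved apart, with Ccl4 5.25-fold higher and Ccl5 4.21-fold lower, from 7.92 in wild type to 5.85. Gzmm, a granzyme, differed by 1.09 on the log2 scale, close to the threshold. The list's median was 1.81, at percentile 99.96 of the random lists. Among 12 chemokine receptors, 5 were higher and 1 lower, the median of 2.98 exceeded all 10000 random lists, and this list shares members with the memory-like one, Cxcr3 among them. Ccr2 and Cxcr5 were higher by 3.59 and 2.38 on the log2 scale, from wild-type signals of 4.50 and 4.06 that lay below the floor. Ccr8 was lower by 2.28 on the log2 scale (-2.28).

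None of the 12 NK receptor genes on the fixed list was listed. The Klra (Ly49) receptors, which NK cells carry, were left off that list and were among the genes with the largest increase. Klra8 was 32.4-fold higher, from 3.54 to 8.56, and Klra10 was 30.8-fold higher. Klra9 was 23.2-fold higher by its brighter probe set, and its other probe set differed by 2.64 on the log2 scale, a gap of 1.90 between both. The Klra genes are close copies of each other, so which member gave the signal is uncertain. Other genes of the 12 largest increases were Ctla2a, at 23.7-fold, Samd3, at 22.8-fold, and Pde2a, a cyclic nucleotide phosphodiesterase, at 13.4-fold.

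Lists tied to IL-4 and to PLZF-expressing innate T cells had few listed members. Il4ra, a chain of the IL-4 receptor, was 2.68-fold higher and was the only listed member of the 12 for IL-4 and STAT6. Of the 12 genes for PLZF-expressing cells, Cxcr6 was 2.83-fold higher and Slamf1 was 2.14-fold lower, and the median of both was 0.20. Zbtb16, which encodes PLZF, and Il4 were not listed. Ifi44 and Iigp1 were 2.12-fold and 2.19-fold higher and were the listed members of 21 interferon response genes. Of the 500 probe sets nearest in mean signal, 5.0% and 4.2% differed by as much as Ifi44 and Iigp1, and 7.8% by as much as Slamf1.

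Genes of immature double-positive thymocytes were lower in CIITAtgpIV-/- in all 7 listed members of the 10 on the list, of which 6 passed the floor. Rag1, which cuts DNA in receptor gene rearrangement, was 32.7-fold lower, from 9.51 in wild type to 4.47. Cd24a, a surface protein lost as thymocytes mature, was 33.1-fold lower, from 8.56 to 3.51. Dntt, the terminal transferase that adds nucleotides at receptor joints, was 20.7-fold lower, and Arpp21 was 10.6-fold lower. Haemoglobin and myeloid RNA was lower in this library too. Ptcra, the invariant pre-T cell receptor chain, differed least, by -1.19 on the log2 scale. The median of the 6 past the floor was -3.89, at percentile 0.01 of the random lists. The file places Rag1 on chromosome 2 (101478439 to 101489689) and Cd24a on chromosome 10 (43298975 to 43304073). Ly6d and Marcks, among the 12 largest decreases, were 35.9-fold and 33.8-fold lower, and Aqp11 was 20.5-fold lower.

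All 18 cell cycle genes were listed and all 18 were lower in CIITAtgpIV-/-, with a median of -2.98 at percentile 0.01 of the random lists. Bub1, a mitotic checkpoint kinase, was 22.9-fold lower, from 8.93 to 4.41, and the cyclins Ccna2 and Ccnb1 were 17.7-fold and 15.9-fold lower. Rrm2, a subunit of ribonucleotide reductase, was 15.3-fold lower. The replication genes Pcna and Mcm2 differed least, by -1.11 and -1.15 on the log2 scale. Kif11, a mitotic kinesin, Shcbp1 and the histone gene H2ac4 were also among the 12 largest decreases, at 18.7-fold, 16.3-fold and 19.8-fold. Haemoglobin and myeloid RNA was lower in this library as well, which does not show that red or myeloid cells carried the cell cycle RNA. A difference in the sort cannot be told apart from one in the genotype.

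Lists for T cell receptor signalling and other T cell subsets were sparsely represented. Of 16 genes of T cell receptor signalling, Nr4a1, Tnfrsf9 and Ikzf2 were 2.96-fold, 3.38-fold and 4.73-fold lower and Bcl2l11, a pro-apoptotic gene, was 2.15-fold higher, with a list median of -1.66 at percentile 22.3. Ikzf2 also belongs to the list for regulatory T cells, whose listed members Ikzf2, Il2ra and Ctla4 were all lower (median -1.52, percentile 39.7). Itgb7 was the only listed gene of late thymic maturation, at -1.22. No gene of the lists for the CD8 lineage, the CD4 lineage, core T cell identity or gamma delta T cells was listed, Cd8a and Cd4 included.

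**Figure D2:**
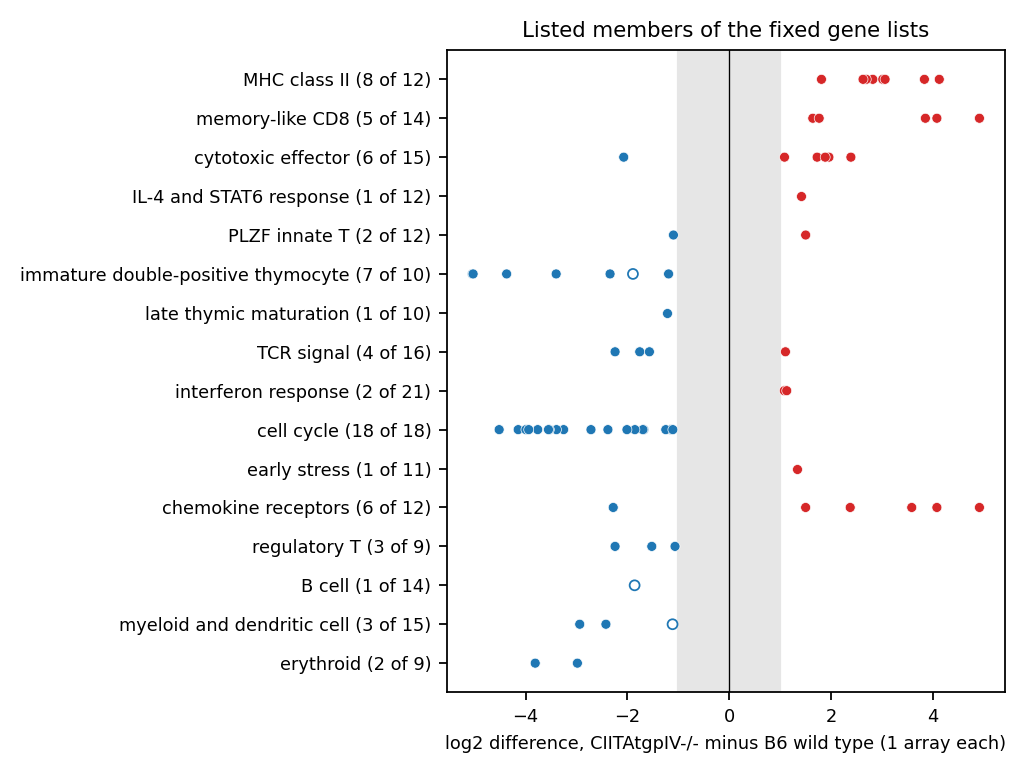
Log2 difference, CIITAtgpIV-/- minus B6 wild type (1 array each), of each gene that the authors listed among the members of the fixed gene lists, with the number listed and the list's size beside each name. Red points are higher and blue points lower, open points lie below the expression floor of 5.42, and the grey band marks differences under 2-fold, which have no gene names in the files; the 18 cell cycle genes all lie to the left and the 8 class II genes all to the right.

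Markers of red cells, myeloid cells and B cells, which a magnetic sort could leave in, were lower in CIITAtgpIV-/- wherever they were listed. Those listed were 2 of 9 red cell, 3 of 15 myeloid and dendritic and 1 of 14 B cell genes, and 72.6% of all listed genes were lower. The Klra receptors, which NK cells carry, were higher, while none of the 12 genes on the NK receptor list was listed. Whether NK cells contributed was not tested. Of the red cell transcripts, Hbb-b1 went from a wild-type signal of 8.48 to 4.67 and Hba-a1, 7.90-fold lower, from 8.51 to 5.53. The macrophage genes Lyz2 and Mpeg1 were 7.66-fold and 5.36-fold lower, from 6.37 and 6.36. Itgax, of dendritic cells, and Jchain, of plasma cells, were also lower but below the floor in both arrays. No granulocyte or thymic epithelial gene was listed. As to RNA quality, Jun was 2.52-fold higher and was the only listed member of 11 early stress genes, no ribosomal protein gene of the list was listed, and no member of the mitochondrial list was named in the file. All 7 probe sets that the file places on the mitochondrial genome without a gene symbol were higher, by 1.03 to 1.60 on the log2 scale.

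Near Ciita, the gene altered by the promoter IV allele, linked sequence of another strain can change measured levels. None of the 58 protein-coding genes within 5 Mb of Ciita in the RefSeq table was listed, where the overall share of listed genes, 3.41%, would give 1.98. Within 20 Mb, 4 of 264 genes were listed (Cdc45, Rfc4, Nmral1 and 2610318N02Rik), all of them lower, a share of 1.52%. The file places the brighter of the 2 probe sets of 2610318N02Rik on chromosome 18. It places the other on chromosome 16, like the other genes named, and both were lower.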

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

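The test of the trend with signal was chosen before its result was seen. Probe sets that the authors' deposited table leaves out, with identifiers outside its range, carried a difference between the arrays. Of these 6996 probe sets, 609 were at least 2-fold higher in CIITAtgpIV-/- and 74 at least 2-fold lower, against 279 higher and 724 lower among the 28560 inside the range. They are singled out because none of the report's counts of changed probe sets and genes includes them and their signal was higher in the CIITAtgpIV-/- array, with medians of 5.33 and 4.94. Most of the difference lay in the 6719 with lower identifiers than any listed (605 higher and 74 lower, median difference 0.23), while the 277 with higher identifiers had 4 higher and 0 lower and a median difference of 0.072. The median difference of all 6996 was 0.22, while probe sets inside the range with the same mean signal had a median of 0.037 (95% of 1000 draws between 0.029 and 0.045), so the trend of the difference with signal was too small to account for it. What these probe sets measure is not annotated in the files used here, so a difference in background, in unspliced RNA or in labelling may underlie the shift, and no biological explanation was tested. Probe set 10339171 had the largest difference, from 4.65 to 9.89.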

How the results depend on the processing

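Gene differences and list medians kept their direction under the alternative normalizations that were run, and counts depended on the floor and the threshold. All 52 genes that the naming rule selected kept their direction and stayed past 2-fold under median centring, quantile normalization, loess and the mean over probe sets, and 207 of the 208 alternative values moved by less than the robust SD of 0.25, the exception being Klra9, at 3.59 as the mean of its probe sets. Over all 789 listed genes with a symbol, the direction was kept under each of these alternatives, while 13 came under 2-fold with median centring, 29 with quantile normalization and 24 with loess, none of them named in the report. The kept direction is a weak check, since every listed gene differed by at least 2-fold from the outset. Median centring, quantile normalization and loess moved each by less than 0.25. Quantile normalization moved the median over the listed range from 0.03 to -0.02. With the floor at the 75th percentile, 160 probe sets were higher and 422 lower, and 125 genes were higher and 316 lower. At 1.5-fold, 738 probe sets were higher and 1424 lower. At 3-fold, 85 probe sets (81 genes) were higher and 341 probe sets (283 genes) lower. Counting probe sets with identical values once, an alternative chosen after seeing the data, gave 252 higher and 621 lower. Of 89 alternative list medians, none changed direction and 82 moved by less than 0.25. With the floor at the 75th percentile only Cxcr6 was left of the list for PLZF-expressing cells, and the medians were -4.37 for immature thymocytes, -3.25 for the cell cycle, 3.84 for chemokine receptors and -2.24 for regulatory T cells (1 gene left). With no floor they were -3.40 for immature thymocytes and -2.42 for myeloid cells, because dim members entered. A window of 20 Mb around Ciita held 4 listed genes and that of 5 Mb held 0. Gene counts at 1.5-fold and under other normalizations were not run, because probe sets under 2-fold have no gene names. No paired analysis was possible because each group has 1 sample, and leaving out a sample was not possible for the same reason. Below the floor, signal over background limits the folds, which then depend on the background correction.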

Other observations

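Gene groups in this part were picked after their values were seen, from symbols or from the gene ontology terms of the authors' deposited table. All 37 listed histone genes were lower in CIITAtgpIV-/-, by up to 4.30 on the log2 scale (-4.30), as were all 33 listed genes annotated to DNA repair. Some histone genes had nearly the same values, H3c7 and H3c8 among them (12.9 in wild type, 10.3 in CIITAtgpIV-/-). Their probe sets may share signal, so the 37 may not be separate observations. Several DNA repair genes, Brca1 and Chek1 among them, also belong to the cell cycle group that follows. Of 145 listed genes annotated to the cell cycle, cell division, mitosis or DNA replication, 139 were lower. A few listed enzymes of sterol and fatty acid synthesis were also lower, with Idi1 at -1.76, Sqle at -1.67, Hmgcs1 at -1.07 and Fads2 at -2.84. Of all 789 listed genes, 72.6% were lower. Surface receptors Itgae, the integrin chain that binds E-cadherin, and Itga4 were 5.78-fold and 5.27-fold lower, and the transcription factor Sox4 was 5.61-fold lower.

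Of 7 listed genes with an interleukin receptor symbol, 5 were higher in CIITAtgpIV-/-, among them Il10ra (1.79), Il10rb (1.60) and Il15ra (1.28), while Il12rb2 was lower (-1.56). Stat4, which transmits IL-12 signals, was 3.42-fold higher. Gpr183, a receptor for oxysterols, was 7.58-fold higher, Entpd1, an enzyme that degrades extracellular ATP, was 8.50-fold higher, and Rgs1, a regulator of G protein signalling, was 5.89-fold higher. The class Ib genes H2-Q6, H2-Q8 and H2-Q10 were higher by 1.76, 1.37 and 1.15, but they are close copies of other class I genes and their probe sets may share signal, which was not tested. All 12 listed probe sets of small nucleolar RNAs and their host genes were higher, with a median difference of 1.09.

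In the remaining paragraphs, the loess test was chosen before its result was seen, and all other tests after. The lower level of immature and cell cycle genes could come from the sort as well as from the genotype. A trend between the arrays with signal does not account for it, since the cell cycle median was -2.97 after loess. If the wild-type sort held more red cells, myeloid cells or B cells, transcripts that CD8 cells do not make should be lower too, and 6 of the 6 listed red cell, myeloid and B cell markers were lower, 2 of them below the floor. This is weak evidence, since these are 2 of 9 red cell, 3 of 15 myeloid and 1 of 14 B cell genes on the lists, and 72.6% of all 789 listed genes were lower. These markers cannot show whether immature thymocytes were left in the sort, since such cells would not carry them. A smaller share of immature and cycling cells among the CD8 cells of CIITAtgpIV-/- mice was not tested apart from the pattern itself: that 25 of the 25 listed immature and cell cycle genes were lower is the pattern to be explained and gives no support. With 1 library per genotype, a difference in the sort and one in the genotype cannot be told apart. The hypothesis that purity contributed is open to a check by flow cytometry of the sorted cells.

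The higher level of MHC class II genes is a pattern that antigen-presenting cells in the CIITAtgpIV-/- sort might also give. Such cells would bring their own transcripts, but the 2 myeloid markers past the floor were lower, the nearest to 0 being Mpeg1 at -2.42, and so were the 3 immunoglobulin probe sets past the floor, the nearest to 0 at -1.25. The 2 myeloid markers, both macrophage genes, argue against macrophages in that sort as the source. They are 2 of the 15 myeloid and dendritic genes on the list, and Itgax, of dendritic cells, was below the floor in both arrays. The immunoglobulin probe sets had wild-type signals of 5.70 to 6.21, near the floor, and 13 of the 14 B cell genes were not listed. All 4 listed genes with a Cd209 or Clec symbol, a group of myeloid lectins, were lower too (-1.68 to -1.10). Of these, Cd209a and Clec12a had wild-type signals of 6.02 and 5.49, also near the floor, and 72.6% of all listed genes were lower. With 1 library per genotype and such dim signals, these values go against dendritic or B cells in direction but cannot settle whether they contributed. Another H2 haplotype or sequence does not account for Cd74, which was higher by 3.02 and lies on chromosome 18, outside the H2 complex. For the 7 listed class II genes of chromosome 17, which were higher by at least 1.81, it cannot be told apart from regulation by the transgene, because the files hold no sequence. A candidate explanation is expression of class II genes in the thymocytes themselves under the CIITA transgene, which remains untested here; staining of class II protein on CD8 thymocytes by flow cytometry would test it.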
